A study of Homo sapiens with 2 samples.

How the data were processed

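RNA sequencing libraries were made with an Illumina TruSeq kit from 1000 ng of total RNA of dermal microvascular endothelial cells grown to 80% confluence, per the labels. The labels hold 2 sample records, 1 untreated and 1 exposed for 24 hours to LL-37 along with poly IC, and each names 4 libraries. No label says whether the libraries came from separate cultures or donors, so the authors' p-values measure only the spread between those libraries, which may be technical.

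Reads were aligned with TopHat2 2.0.8 and analysed in Partek, per the submitters' processing notes. These notes name the genome build mm10, a mouse build, while the cells are human and the deposited gene names are human symbols, so the build behind the values is uncertain. The read counter, the gene annotation and the statistical model are not given in the sources used here. The deposited gene table holds 2076 genes with different names, none with a fold under 1.5. For each gene it gives the authors' least-squares mean per group, a normalized expression signal whose unit is not stated, per the file headers. A total of reads is also deposited as a signal, with values from 10.0 to 26400 and a median of 42, which are not all whole and come to a median of 9.95 times the sum of the 2 group means. The deposited ratio is the treated mean divided by the untreated mean, which held within 2% for all 2076 genes, and the authors' fold change is a signed score, the ratio itself or, for lower genes, minus its inverse. The authors' p-value and step-up FDR per gene are used as deposited. A second deposited table gives −log10 of a p-value for each of 20 gene ontology terms, with tool and background not stated per the file headers.

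No values per library were used, and 0 columns of such values were left out, so no test of the 2 groups was run here and the authors' FDR was taken instead: genes at 0.05 or under are called risen or fallen. Because no depth is known, no counting interval or floor could be given. The deposited total of reads was not taken as a depth, since its scale is not stated. From the smallest p-value and its FDR the authors tested about 10934 genes (10917 to 10952 given rounding), of which about 4089 were past 0.05, so about 2451 past genes changed by less than 1.5-fold or were not analysed here. Counts here cover listed genes only.

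The gene lists, the test of their direction, the rule for named genes and most alternatives were fixed before the data were examined. For each of 24 lists, the higher and lower members among the listed genes were compared with all other listed genes by a two-sided Fisher's exact test when at least 3 members were listed, with Benjamini-Hochberg adjustment over the 18 lists tested. List members were matched by current or older symbol with the RefSeq gene table of GRCh38.p14. Counts adjusted over the list alone apply Benjamini-Hochberg to the authors' p-values of the list's members, with unlisted members at a p of 1. Named genes are the 6 called genes with the largest fold in each direction and, per list with at least 3 listed members, the 3 (first 8 lists) or 2 members (other lists) with the largest fold in the list's more common direction, leaving out genes whose authors' mean lies under the 10% point of the listed genes (0.837) in both groups. Smaller lists are given by all their listed members. For 1 of the lists, a gene that the rule names is not reported here. The other named genes, such as ISG15, MX1, KLF4, CDKN2B and TNFRSF10D, were chosen after their values were seen.

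Gene classes and positions come from the GENCODE 29 basic annotation of GRCh38, in which 1518 of the 2076 names matched and 558 did not, most of them clone-based names, and 1 name had been turned into a date by a spreadsheet. A pseudogene was paired with the protein-coding gene whose symbol it carries before its P and number. Gene length is the genomic span from first to last base, and exon length the union of exons. Re-pairing tests used 10000 draws, correlations 100000 permutations, and slopes 95% bootstrap intervals.

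The list test was tested on simulated directions for the 2076 genes. With no list changed, at least 1 of the 18 lists was called in 2% of 200 draws. Each gene's direction was drawn on its own, so this share does not hold for genes that move together. Of lists given 90% higher members, 93.4% were called where at least 10 members were listed (5 lists) and 13.6% where fewer were (4 lists). These 4 lists had 7 (MHC class I), 4 (matrix), 3 (scavenger receptors) and 3 (unfolded protein) listed members. With 3 listed members no split could have passed the threshold, which lowers the 13.6%. The test therefore has little reach in lists of 3 or 4 listed members. Its reach in the larger of the lists under 10 was not given apart. No list was given mostly lower members, so the reach of the test for lists that lean lower is not known. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. Alternatives covered stricter fold and FDR limits, gene classes, low means, the background and shared or leading list members.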

Results

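RNA was sequenced from primary human dermal microvascular endothelial cells, the cells that line the small vessels of the skin. One group was left untreated and the other was given poly IC together with LL-37 for 24 hours. Poly IC is a synthetic double-stranded RNA that cells sense as they would viral RNA. LL-37 is an antimicrobial peptide of the skin that binds nucleic acids. Each group is 1 sample record whose label names 4 libraries, and the comparison of the groups asks how the cells' transcripts changed under the combined treatment. Treatment with poly IC or LL-37 alone was not analysed here, so the share of each agent in a change cannot be given. The values are the authors' mean per group, fold change, p-value and step-up false discovery rate (FDR) for 2076 genes that passed a 1.5-fold change. Values per library were not used here, so no spread between replicates stands beside a value, and the sequencing depth of the libraries is unknown.

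Interferon-stimulated antiviral genes rose by up to 689-fold (from an untreated mean of 0.0961) in cells given poly IC with LL-37, per the authors' deposited table, while most genes that fell did so by small amounts. Of the 2076 listed genes, 785 were higher and 1291 lower in treated cells. At an FDR of 0.05 or under, 664 genes rose and 974 fell in the authors' deposited table. The median fold of the genes that rose was 2.18 (quartiles 1.76 and 3.79), and that of the genes that fell was 1.68 (quartiles 1.58 and 1.89), both taken over the authors' deposited table. Among called genes with a change of at least 4-fold, 155 rose and 9 fell, and all 65 with a change of at least 10-fold rose.

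The called gene with the largest rise was CXCL10, a chemokine that draws activated T cells, whose authors' mean went from 1.18 to 991, an 838-fold change (FDR 6.67e-20) in the authors' deposited table. It was followed in the authors' deposited table by the antiviral gene OASL (689-fold, FDR 0.000461), the chemokine CXCL11 (610-fold, FDR 5.74e-09) and the antiviral genes RSAD2 (499-fold, FDR 0.0128) and IFIT1 (479-fold, FDR 1.78e-10). The sixth was AP001610.5, which has no match in the annotation used here (327-fold, FDR 0.0204 in the authors' deposited table). In the GENCODE 29 annotation of GRCh38, CXCL10 lies on chromosome 4 from 76021117 to 76023497 and CXCL11 from 76033682 to 76041415, with CXCL9 on their other side from 76001275 to 76007488.

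Falls were smaller. Among protein-coding genes, CXCR4, a receptor of the chemokine CXCL12, fell 5.83-fold (authors' mean 25.2 to 4.31, FDR 6.48e-09) in the authors' deposited table. The sulfotransferase gene CHST1 fell 5.23-fold (FDR 3.14e-07) and MEX3B, which encodes an RNA-binding protein, fell 4.66-fold (FDR 0.00206), per the authors' deposited table. The other 3 of the 6 largest falls were the long noncoding RNAs DANCR (5.32-fold, FDR 1.54e-05) and AC012360.2 (5.80-fold, FDR 0.0146) and the unmatched RP11-391M1.4 (6.43-fold, FDR 0.00205) in the authors' deposited table.

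**Figure D1:**
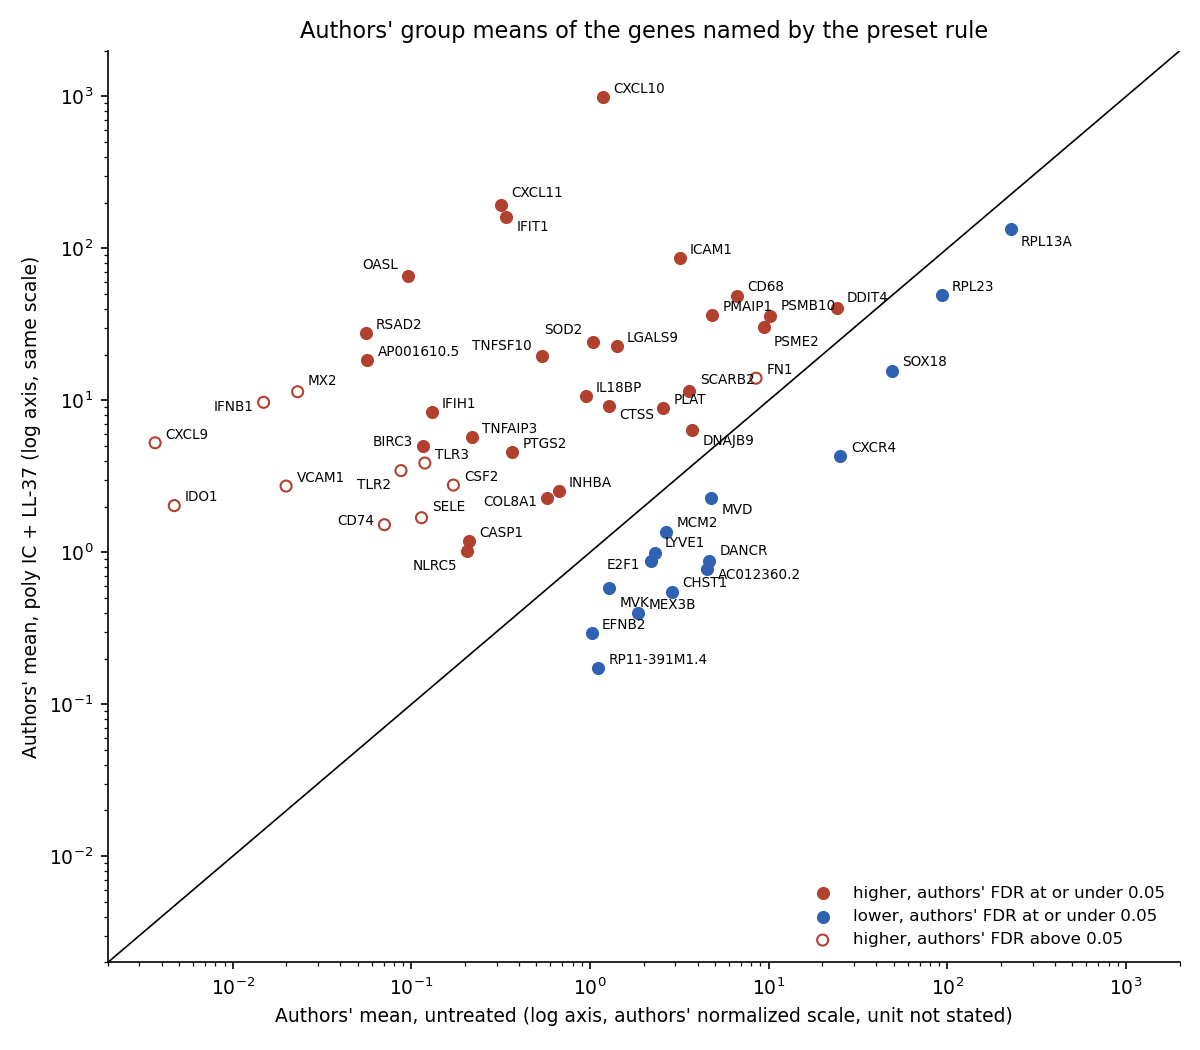
The authors' mean of the genes named by the preset rule in untreated cells (horizontal) and in cells given poly IC + LL-37 (vertical), both on log axes on the authors' own scale, with the line of equal means. Red points are higher and blue points lower in treated cells, and open points have an authors' FDR above 0.05: CXCL10 stands at 1.18 and 991, while CXCL9 (0.00368 and 5.26) and IDO1 (0.00471 and 2.03) are open points with untreated means close to 0.

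Of the 24 preset gene lists, 18 had at least 3 listed members, and in 10 of them the direction of the members differed from that of the other listed genes (two-sided Fisher's exact test, adjusted p at or under 0.05). Of those 10 lists, 9 leaned towards higher and 1 towards lower. Interferon-stimulated antiviral effectors formed the largest of them. All 52 listed members were higher, against 36.2% of the other listed genes (Fisher's exact test, adjusted p = 6.64e-22). Of them 44 rose past the FDR and 8 did not pass it, and 45 passed when adjusted over the list alone. In the authors' deposited table ISG15, a ubiquitin-like modifier, had the smallest FDR of all listed genes (51.2-fold, authors' mean 34.3 to 1760, FDR 6.67e-44). MX1, a GTPase that restricts RNA viruses, rose 317-fold (FDR 0.000138) and IFIT3 rose 204-fold (FDR 2.43e-13) in the authors' deposited table. Its relative MX2 was listed at 492-fold with an FDR of 0.13 in the authors' deposited table, so its difference was not past the threshold.

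Genes of RNA sensing and interferon signalling were higher in all 15 listed cases (Fisher's exact test, adjusted p = 3.82e-06), of which 13 rose past the FDR, also when adjusted over the list alone. IFIH1, a cytosolic sensor of double-stranded RNA, rose 63.9-fold (FDR 0.0134) and the transcription factor IRF7 23.1-fold (FDR 1.16e-17) in the authors' deposited table. STAT2, which carries the interferon signal to the nucleus, rose 11.3-fold (FDR 8.83e-06) in the authors' deposited table. The membrane receptors TLR2 and TLR3 were listed at 39.4-fold (FDR 0.131) and 32.5-fold (FDR 0.201) in the authors' deposited table and did not pass. Of the interferon genes themselves, only IFNB1 was listed. Its authors' mean was 0.0149 in untreated and 9.71 in treated cells (653-fold, FDR 0.219 in the authors' deposited table), which did not pass the threshold, and 0 of its list passed when adjusted over the list alone.

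Chemokines were higher in all 12 listed cases (Fisher's exact test, adjusted p = 3.65e-05), and 10 rose past the FDR, the number that passed also when adjusted over the list alone. Beside CXCL10 and CXCL11, CX3CL1, a chemokine tethered to the endothelial surface, rose 189-fold (FDR 0.00222) and the monocyte chemokine CCL2 rose 6.74-fold (authors' mean 36 to 243, FDR 1.13e-17) in the authors' deposited table. CXCL9 had the largest fold of the authors' deposited table, 1430, from an authors' mean of 0.00368 to 5.26, with an FDR of 0.534. Inflammatory cytokines and growth factors were higher in all 8 listed cases (Fisher's exact test, adjusted p = 0.00147), and 6 rose, also when adjusted over the list alone. TNFSF10, the death ligand TRAIL, rose 36-fold (FDR 2.77e-06), IL18BP, a soluble inhibitor of IL-18, 11.4-fold (FDR 5.17e-05) and IL6 10.9-fold (FDR 0.0236) in the authors' deposited table. CSF2 was listed at 16.1-fold with an FDR of 0.106 in the authors' deposited table.

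The NF-kB pathway and its feedback genes were higher in all 14 listed cases (Fisher's exact test, adjusted p = 6.82e-06), with 13 past the FDR and 14 when adjusted over the list alone. BIRC3, an inhibitor of apoptosis, rose 43.1-fold (FDR 0.038), the deubiquitinase gene TNFAIP3 26.2-fold (FDR 0.0121) and the mitochondrial superoxide dismutase gene SOD2 23.2-fold (FDR 2.33e-08) in the authors' deposited table. NFKBIA, which encodes the inhibitor that holds NF-kB in the cytoplasm, rose 4.93-fold (FDR 6.25e-16) in the authors' deposited table.

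**Figure D2:**
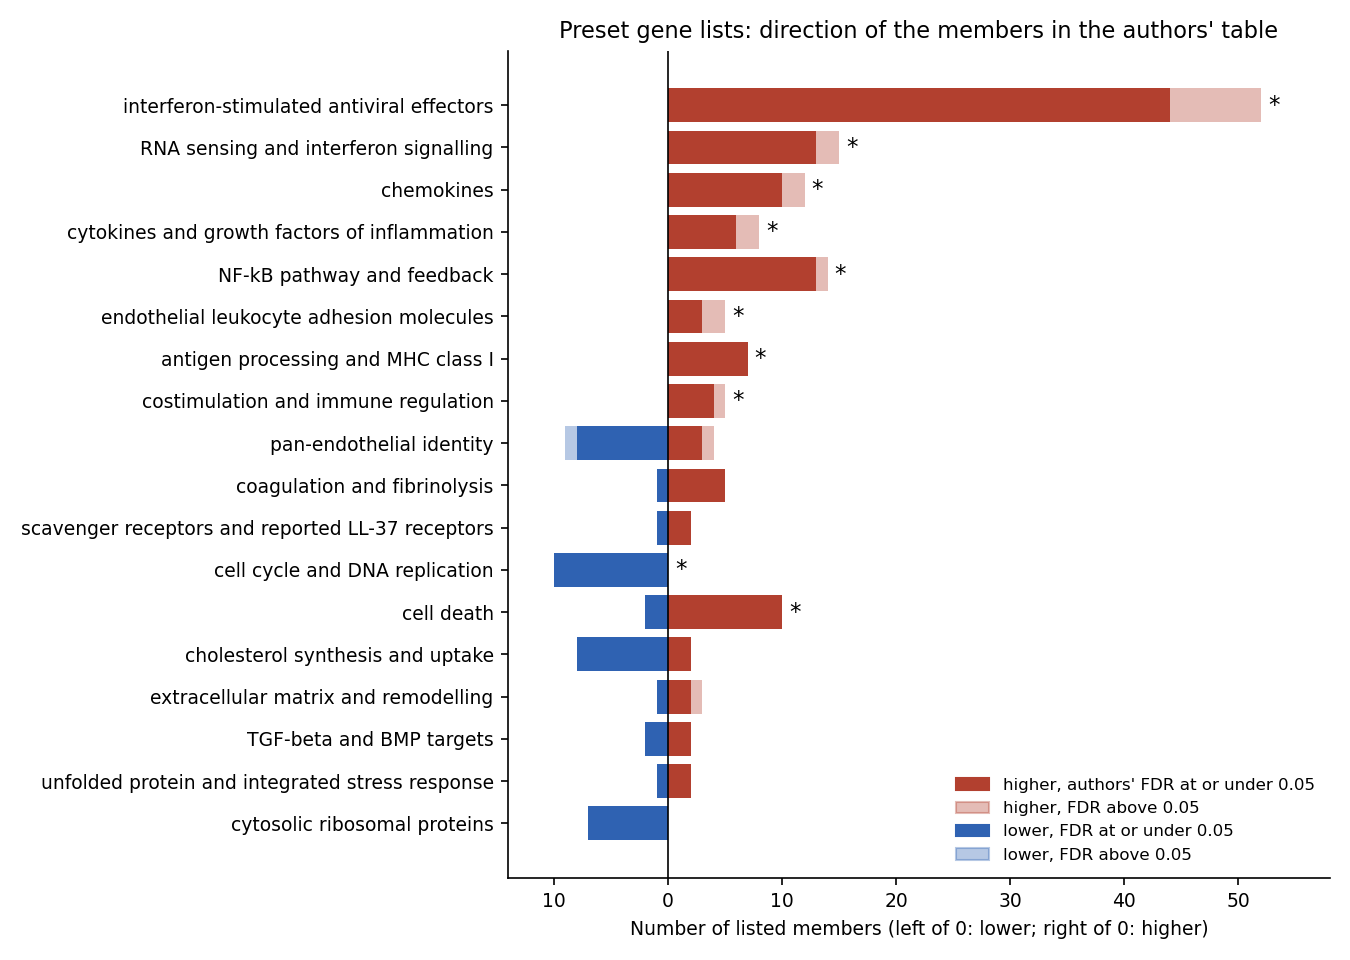
Number of listed members of each preset gene list that were higher (red, right of 0) or lower (blue, left of 0) in cells given poly IC + LL-37, for the 18 lists with at least 3 listed members. Full colour marks an authors' FDR at or under 0.05 and pale colour an FDR above it, and a star marks an adjusted p of Fisher's exact test at or under 0.05: antiviral effectors hold 44 called and 8 other higher members, and the cell cycle list is the starred list with members on the left only.

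Surface molecules that bind leukocytes were higher in all 5 listed cases (Fisher's exact test, adjusted p = 0.0153), and 3 rose past the FDR, also when adjusted over the list alone. ICAM1, a ligand of leukocyte integrins, rose 27.2-fold (authors' mean 3.17 to 86.3, FDR 2.36e-12) in the authors' deposited table. The others past the FDR were CD47 (4.07-fold, FDR 3.11e-08) and PODXL (1.89-fold, FDR 6.13e-06) in the authors' deposited table. VCAM1 and SELE did not pass, at 138-fold (FDR 0.76) and 14.8-fold (FDR 0.215) in the authors' deposited table. Genes of antigen processing and MHC class I were higher in all 7 listed cases (Fisher's exact test, adjusted p = 0.00326), and all 7 rose past the FDR, also when adjusted over the list alone. NLRC5, an activator of class I genes, rose 4.96-fold (FDR 0.00334), the immunoproteasome gene PSMB10 3.54-fold (FDR 4.29e-06), the proteasome activator gene PSME2 3.23-fold (FDR 2.12e-08) and B2M, the light chain of class I molecules, 3.13-fold (FDR 2.8e-34) in the authors' deposited table. Of the 20 members of this list, the 12 that lie between 28.5 and 33.5 Mb of chromosome 6 in GRCh38 were not analysed here, since none is among the 2076 genes, and 7 of the other 8 are listed.

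Of the 11 members of the MHC class II list, the 8 that lie in the same stretch of chromosome 6 were not analysed here; 2 of the other 3 were listed and 1 rose, also when adjusted over the list alone. CTSS, a protease that trims the class II invariant chain, rose 7.18-fold (FDR 0.00032), and CD74, the invariant chain, was listed at 21.5-fold with an FDR of 0.203 in the authors' deposited table. Costimulation and immune regulation genes were higher in all 5 listed cases (Fisher's exact test, adjusted p = 0.0153), with 4 past the FDR, also when adjusted over the list alone. LGALS9, which encodes galectin-9, rose 16.2-fold (FDR 4.45e-09) and the checkpoint ligand CD274 2.75-fold (FDR 0.000665) in the authors' deposited table. IDO1, which breaks down tryptophan, was listed at 431-fold with an FDR of 0.921 in the authors' deposited table.

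Endothelial identity genes moved both ways, with 3 higher and 8 lower past the FDR among 13 listed, 11 when adjusted over the list alone, and the lean of the list was not past the threshold (Fisher's exact test, adjusted p = 0.777). EFNB2, a marker of arterial endothelium, fell 3.48-fold (FDR 1.2e-05), the transcription factor SOX18 fell 3.11-fold (authors' mean 48.8 to 15.7, FDR 0.000169) and NOS3, the endothelial nitric oxide synthase, fell 1.61-fold (FDR 0.000235) in the authors' deposited table. KLF4, a transcription factor of quiescent endothelium that is also induced by inflammatory signals, rose 32-fold (FDR 0.00288), and the angiopoietin receptor TEK rose 1.68-fold (FDR 0.00182) in the authors' deposited table. Of the lymphatic markers 1 was listed and passed, also when adjusted over the list alone: LYVE1 fell 2.32-fold (FDR 0.000125) in the authors' deposited table. No member of the keratinocyte, fibroblast and mural, or leukocyte marker lists was among the 2076 genes (0 of 12, 0 of 14 and 0 of 11), which leaves open whether they were below 1.5-fold, not expressed or not analysed here for another reason.

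Coagulation and fibrinolysis genes included 5 that rose and 1 that fell of 6 listed, all 6 of them past the threshold when adjusted over the list alone, and the lean of the list just missed the threshold (Fisher's exact test, adjusted p = 0.0517). PTGS2, the inducible cyclooxygenase, rose 12.4-fold (FDR 0.0165) and PLAT, the tissue plasminogen activator, 3.48-fold (FDR 7.91e-08), whereas the urokinase gene PLAU fell 1.61-fold (FDR 1.31e-08) in the authors' deposited table. Of the scavenger and reported LL-37 receptors, 3 were listed, 2 rose and 1 fell, all 3 also when adjusted over the list alone (Fisher's exact test, adjusted p = 0.631). With only 3 listed members no split could have passed the threshold, so the test decides nothing for this list. CD68 rose 7.38-fold (FDR 1.77e-12), SCARB2, a lysosomal membrane protein gene, rose 3.21-fold (FDR 1.01e-06) and SCARA3 fell 1.58-fold (FDR 0.000991) in the authors' deposited table.

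Cell cycle and DNA replication genes were lower in all 10 listed cases, each past the FDR and also when adjusted over the list alone (Fisher's exact test, adjusted p = 0.0301). The other 34 of the list's 44 members were not listed, so most of the list showed no 1.5-fold change or was not analysed here. E2F1, a transcription factor of S-phase entry, fell 2.48-fold (FDR 6.66e-09) and MCM2, a subunit of the replicative helicase, 1.96-fold (FDR 1.02e-07) in the authors' deposited table. One of the 10 is CDKN2B, a cyclin-dependent kinase inhibitor that restrains the cycle, which fell 1.86-fold (FDR 2.82e-06) in the authors' deposited table. Cell death genes leaned towards higher, with 10 that rose and 2 that fell of 12 listed, all 12 also when adjusted over the list alone (Fisher's exact test, adjusted p = 0.00426). PMAIP1, the pro-apoptotic NOXA, rose 7.55-fold (FDR 1.16e-12), the inflammatory caspase gene CASP1 5.60-fold (FDR 7.02e-05) and the necroptosis effector MLKL 3.83-fold (FDR 6.44e-09) in the authors' deposited table. The 2 that fell were the TRAIL decoy receptors TNFRSF10D (3.90-fold, FDR 5.82e-23) and TNFRSF10C (1.92-fold, FDR 0.00695) in the authors' deposited table. The 10 that rose also include CFLAR, an inhibitor of apoptosis (2.59-fold, FDR 5.49e-06 in the authors' deposited table). The lean of the list thus gives no direction for cell death itself.

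Cholesterol synthesis and uptake genes were mostly lower, 8 against 2 that rose of 10 listed, all 10 also when adjusted over the list alone, a split whose difference from the other listed genes did not pass the threshold (Fisher's exact test, adjusted p = 0.432). The mevalonate pathway genes MVK and MVD fell 2.19-fold (FDR 3.8e-12) and 2.08-fold (FDR 2.89e-05), while CH25H, whose product 25-hydroxycholesterol is antiviral, rose 3.14-fold (FDR 8.77e-05) in the authors' deposited table. All 7 listed cytosolic ribosomal protein genes fell, also when adjusted over the list alone, and the lean of the list missed the threshold (Fisher's exact test, adjusted p = 0.0742). The other 34 of the list's 41 members were not listed. RPL23 fell 1.89-fold (FDR 0.00304) and RPL13A 1.69-fold (authors' mean 226 to 134, FDR 0.00915) in the authors' deposited table; these genes have many pseudogenes in the same table, so their values are uncertain.

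In each of the remaining lists only 3 or 4 members were listed, and the test, which has little reach at that size, did not pass its threshold. Of 4 listed matrix genes 2 rose and 1 fell, 3 in all when adjusted over the list alone, and 75% of the listed members were higher against 37.7% of the other listed genes (Fisher's exact test, adjusted p = 0.214). They included COL8A1 at 3.98-fold higher (FDR 7.71e-05), while FN1, fibronectin, did not pass at 1.64-fold (FDR 0.0571), in the authors' deposited table. Of 4 listed TGF-beta and BMP targets 2 rose and 2 fell, all 4 also when adjusted over the list alone (Fisher's exact test, adjusted p = 0.673). INHBA, a subunit of activins, rose 3.79-fold (FDR 0.00276) and the bone morphogenetic protein gene BMP4 fell 2.04-fold (FDR 2.77e-07) in the authors' deposited table. Of 3 listed genes of the unfolded protein and integrated stress response 2 rose and 1 fell, all 3 also when adjusted over the list alone (Fisher's exact test, adjusted p = 0.631). Here too no split of 3 members could have passed the threshold. DNAJB9 and DDIT4 rose 1.70-fold (FDR 6.11e-05) and 1.69-fold (FDR 3.95e-05) in the authors' deposited table.

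The list test compares directions among genes past 1.5-fold only, treats genes as independent and says nothing of genes not listed. Unlisted were 17 of 32 members for RNA sensing, 16 of 24 for cytokines, 10 of 15 for adhesion, 7 of 12 for costimulation and 17 of 29 for cell death. Most listed genes are lower, so a lean towards lower is harder to call. All 5 listed adhesion genes being higher passed, while all 7 listed ribosomal protein genes being lower did not. Among genes of at least 2-fold, 6 of the 10 calls ended (RNA sensing, cytokines, adhesion, MHC class I, costimulation and cell death), those of adhesion and costimulation also ended among genes past the FDR, and that of the cell cycle ended against a background without other list members (Fisher's exact test, adjusted p = 0.0601).

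Large folds and small FDRs did not always go together. Of 104 genes with a ratio of at least 10, 65 passed the FDR and 39 did not, and the median of the authors' mean in untreated cells was 0.542 in the former and 0.0708 in the latter, taken over the authors' deposited table. In treated cells these medians were 19.5 and 2.42, so the genes that did not pass had lower medians in both groups. For genes such as CXCL9, IDO1 and IFNB1 the fold rests on an untreated mean close to 0 and its size is uncertain. That limit holds as well for called genes with some of the largest folds, since the untreated means of OASL, RSAD2 and AP001610.5 were 0.0961, 0.0554 and 0.0566 in the authors' deposited table.

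By annotation, 1148 of the listed genes were protein-coding, of which 507 rose and 534 fell, and 295 were pseudogenes, of which 49 rose and 169 fell past the FDR. A parent gene was listed for 142 of the pseudogenes, over 60 parents, and 141 of these pairs had the same direction in both. The exception was IMPDH1P10, at 1.74-fold higher (FDR 0.116), against its parent IMPDH1 at 1.75-fold lower (FDR 1.76e-09), in the authors' deposited table.

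**Figure D3:**
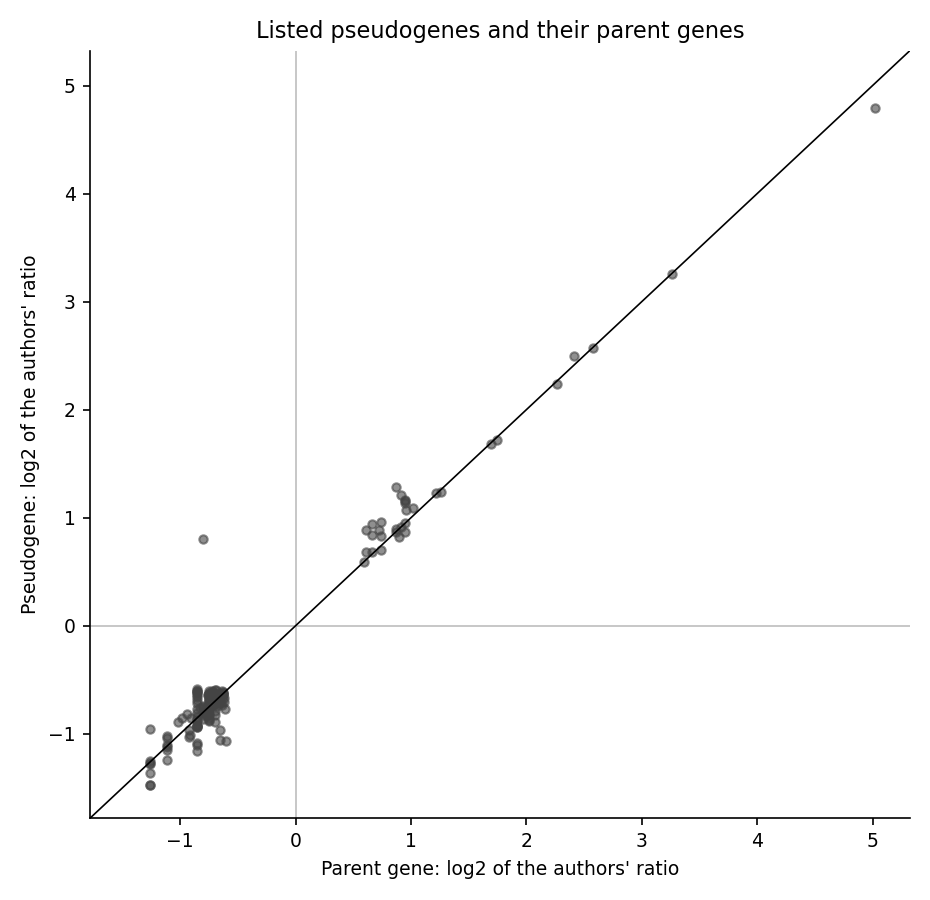
Log2 of the authors' ratio of treated to untreated cells for listed pseudogenes (vertical) against that of their listed parent genes (horizontal), 1 point per pseudogene, with the line of equal ratios. Not all of the 142 pairs are drawn. All pairs but 1 lie below 0 on both axes or above 0 on both, and most lie close to the line.

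A second deposited table ranks 20 gene ontology terms for a comparison whose name differs from that of the 2 sample records, so it is described on its own. Defense response to virus led the authors' deposited table with a −log10 p of 20 and 26 in brackets after the term, a number the table does not explain. Type I interferon signaling (12.3) and interferon-gamma-mediated signaling (11.7) came next in the authors' deposited table, and positive regulation of NF-kappaB activity had 8.17. Inflammatory response (5.52) and angiogenesis (4.12) came lower, and nucleoplasm was last (3.46) in the authors' deposited table.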

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

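The limits on gene class and those without an FDR limit or with lists at an FDR of 0.05 were chosen after seeing the data, and the others were planned. The 664 genes that rose became 385 at 2-fold and 155 at 4-fold or more, and the 974 that fell became 176 and 9. At an FDR of 0.001 or under 584 genes fell, and among protein-coding genes alone 534 did. Under the other alternatives run, both counts stayed within 1.5 times. The 10 lists past the threshold became 3 among genes of at least 2-fold, where 65.6% of the listed genes are higher and fewer genes are tested, and between 8 and 11 under the other alternatives. Across lists and alternatives, 120 of 135 values kept their direction and their side of the threshold, 11 lost the call and 2 gained it, which were coagulation with list members out of the background and ribosomal proteins among protein-coding genes. At 2-fold or more the cell cycle list, among others, kept fewer than 3 members and gave no value. The TGF-beta and BMP list, which never passed, turned to the other side of its background at 2-fold or more (50% of members higher) and without its leading member (33.3% higher). The cause was not tested. Alternatives that need values per library (another normalization, no low-count filter, another pseudocount, leaving out each library) were not run, because the table holds group means. No paired analysis was possible because the columns carry no replicate number. Unknown depth leaves open how much of each fold is counting error, above all where the untreated mean is close to 0.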

Other observations

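All tests in this part were chosen after the values were seen, except that with the parent's exon number. The genes and families of this paragraph and the next were picked because of their values. A test of the 5 families or of the region below would thus carry no weight, and only counts are given. Of 10 listed genes named as Notch ligands, modulators or HES and HEY factors, 9 fell and 1 rose past the FDR, DLL4 and HEY1 among them being members of preset lists as well. NRARP, a feedback inhibitor of Notch, fell 3.24-fold (FDR 1.87e-08), the ligands JAG2 and DLL4 fell 2.77-fold (FDR 7.6e-08) and 2.74-fold (FDR 1.97e-13), and HES4 rose 4.04-fold (FDR 0.000561) in the authors' deposited table. All 8 listed genes of proteasome subunits and regulators rose, from PSMF1 at 1.51-fold (FDR 3.03e-07) to PSMB10 at 3.54-fold (FDR 4.29e-06) in the authors' deposited table, and 3 of them (PSMB10, PSME1 and PSME2) also count in the antigen processing list. All 5 listed butyrophilins rose, led by BTN3A1, whose product helps gamma-delta T cells recognise phosphoantigens, at 5.76-fold (FDR 0.00165) in the authors' deposited table. The 4 listed GIMAP genes, a family of GTPases, rose as well, GIMAP2 by 2.29-fold (FDR 8.65e-10) in the authors' deposited table. Of 7 listed genes named EIF or EEF, 5 fell and 1 rose past the FDR. Some of these genes have listed pseudogenes, so their values are uncertain.

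CXCR4 fell 5.83-fold (authors' mean 25.2 to 4.31) in the authors' deposited table. ACKR3, the other receptor of CXCL12, rose 5.55-fold from a low untreated mean (authors' mean 0.291 to 1.61, FDR 0.0032) in the authors' deposited table. PGF, which encodes placental growth factor, fell 2.87-fold (FDR 8.19e-08), and VASH1, which encodes an endothelial inhibitor of angiogenesis, fell 2.71-fold (FDR 2.48e-05) in the authors' deposited table. VEGFC, a growth factor of lymphatic vessels, rose 3.62-fold (FDR 9.08e-08) and ANGPTL4, an inhibitor of lipoprotein lipase, 13.2-fold (FDR 2.04e-05) in the authors' deposited table. The fatty acid binding protein gene FABP4 fell 2.44-fold (FDR 0.000785), the desaturase gene FADS1 1.97-fold (FDR 8.02e-05) and the fatty acid synthase gene FASN 1.91-fold (FDR 0.00207) in the authors' deposited table. Between 28.5 and 33.5 Mb of chromosome 6, 0 of 181 annotated protein-coding genes are among the genes analysed here, against 5.84% of those elsewhere, and no explanation was tested.

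Of the 295 listed pseudogenes, the 142 whose parent gene also passed 1.5-fold mostly carried a fold close to that of the parent, with exceptions such as IMPDH1P10. The others were not compared. The same direction held in 99.3% of these pairs, against a median of 57.0% when parents were exchanged at random (permutation p = 0.0001, the smallest 10000 draws can give), which argues against transcription of each pseudogene on its own. The median absolute log2 difference within pairs was 0.0754, against 0.174 when parents of the same direction were exchanged (permutation p = 0.0001), so reads shared between the pseudogene and its parent are a candidate explanation. If so, the pseudogenes of such pairs may repeat the change of their parents rather than add to it.

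The deposited total of reads was lower in genes of greater genomic length. Over 1148 protein-coding genes, which are not independent, Pearson's r was -0.419 and Spearman's rho -0.427 on log scales (adjusted permutation p = 1.33e-05 and 2e-05 over 4 relations), which higher expression of genes with short introns could give, and that stays open since no other measure of expression was at hand. Over the 60 parents of the pairs above, each with its pseudogene of the highest total, the log10 ratio of totals (pseudogene over parent) rose with the log10 ratio of genomic lengths (parent over pseudogene) with a slope of 1.09 (95% interval 0.674 to 1.53). Values divided by exon length or by no length would give a slope of 0 only if the parents' expression did not vary with their length. That is left open above, and each pseudogene was picked by its total, so this slope cannot exclude either. With exon length in the fit the slope was 1.41 (0.959 to 1.86), which holds the value of 1 that division by genomic length, introns included, would give. The slope on exon length was -0.924 (-1.58 to -0.245). With the parent's exon number in the fit the slope on genomic length was 0.967 (0.495 to 1.33), and that on exon number 0.907 (0.212 to 1.68). Exon number thus did not account for all of the slope on genomic length. It is only a stand-in for reads across exon junctions placed on intronless pseudogenes, so how much such reads add stays open. A fit on both lengths over the 1148 protein-coding genes gave slopes of -0.477 (-0.564 to -0.389) on genomic length and -0.00596 (-0.172 to 0.159) on exon length, whose intervals do not hold the -1 and 1 that division by genomic length would give if expression did not vary with length, so that division stays open as well.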
